A study of Mus musculus with 13 samples.

How the data were processed

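The samples are striatal total RNA from naïve male C57Bl/6J mice, extracted with Trizol and turned into biotinylated cRNA for Affymetrix arrays, per the labels' protocols. The labels name 13 separate samples: 4 wild type, 5 STEP heterozygous and 4 STEP homozygous. If they are not separate animals, p-values measure only the spread between these samples, which may be technical. Each sample has 1 array, so no depth per sample applies, and the number of arrays limits the precision.

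The deposited series table holds an intensity per probe set and array, a linear PLIER signal (version not given) per the submitters' processing notes. Background correction, between-array normalization and array annotation are not given in the sources used here. Array medians differ, so the authors did not make the array distributions equal. The authors also deposited a table of changed genes. Its expression columns are a deposited score per mouse, whole numbers that round the signals, per the file headers. Its fold change is a deposited score too, signed and linear, with negative values for decreases, and its raw and adjusted p-values are the authors' own, per the file headers. The test behind them is not given in the sources used here. In that table the columns headed for the homozygotes equal the wild-type arrays of the same number, and those headed for wild type equal the homozygous arrays, for 100% of probe sets within a rounding tolerance of 0.5, while the heterozygous columns equal their own arrays. Ptpn5 is low on the arrays that the sample labels call homozygous, the sign of the authors' folds fits those labels, and the sample labels were used throughout. These rounded columns entered no test. Columns per sample left unmapped numbered 0.

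Signals were taken as log2(signal + 16). The 64 control probe sets were left out, and of 45037 others 27022 were kept whose mean over all arrays exceeded the 40th percentile, a signal of about 112. A fold on this scale understates the change of dim probe sets. A single linear model of 3 genotype means over all 13 arrays was fitted with lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3), with contrasts for each pair of genotypes and for heterozygotes against the midpoint of the other genotypes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Group means of single values were compared by two-sided exact permutation tests. The comparisons, tests, gene lists, naming rule and alternatives were chosen before the data were examined, except where the text says otherwise.

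Gene names come only from the authors' deposited table, whose 4423 probe sets include 3581 with 1 gene, 49 with several and 793 with no symbol. Of the 3581, 3543 matched a RefSeq gene table of assembly GRCm38.p6 through their Entrez IDs, which also gave chromosome and distance from Ptpn5; no coordinates are printed, because the build of the array annotation is not given. Of the tested probe sets 2926 have a single gene name and 24096 are unnamed here. Since the authors selected that table on these arrays, gene lists could be measured only through selected genes.

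Of 32 gene lists, 15 had at least 3 measured genes and were tested on the probe set of highest mean per gene with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other named genes. Calls were tested again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. Correlations of effects were set beside 100 simulations with no effect and shared wild-type arrays. Positions near Ptpn5 were tested by Fisher's exact test with a window of 10 Mb.

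The genes named are all Ptpn5 probe sets, then per comparison the genes with the largest changes among those that pass and lie outside the range of the other genotype on every array (12 in each direction for homozygotes against wild type, 5 for the others). Where none besides Ptpn5 passes, the 3 lowest p-values in each direction are named as not passing. Of each list up to 4 members by smallest p in homozygotes against wild type are named, up to 8 passing genes within 10 Mb of Ptpn5 and up to 5 passing genes off the midpoint. Probe sets with several gene names or none are left out of the rule. Other genes are marked as chosen after their values were seen.

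Alternatives were quantile normalization, median centring, an offset of 1, no filter or a 60th percentile filter, other variance models, array weights, fitting only the groups compared, leaving out each array, the replicate number as a block, other thresholds, 1 probe set per gene and other windows. Alternatives added after seeing the data were quantile normalization without a filter, leaving out heterozygous array 5 and homozygous array 4, and a cortical score as covariate. The limma step was tested on simulated data of 27022 probe sets. For homozygotes against wild type it recovered 93% of changes of log2 size 1 and 21% of size 0.5 with 8 false calls, and for heterozygotes against wild type 99% and 33% with 6 false calls. In 100 simulations the list test called a list shifted by 0.5 in 100 and called 0.35 other lists per simulation, some of which share members with it. All these simulations drew probe sets or genes independently, with no array brightness effect and no correlation between genes. On the real arrays random named gene lists had a median residual correlation of 0.258. The false calls of the simulations therefore do not carry over to these arrays. The Y-linked label check could not be made, because none of those genes is named among the probe sets used here. Figures were drawn with matplotlib 3.10.9.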

Results

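Gene expression in the striatum was measured on 13 Affymetrix arrays, each from a separate sample of naïve male C57Bl/6J mice. The samples fall into 3 genotypes: 4 from wild-type littermates, 5 from heterozygotes and 4 from homozygotes for a knockout of STEP. STEP, the striatal-enriched protein tyrosine phosphatase, is encoded by Ptpn5 and dephosphorylates MAP kinases, Src-family kinases and glutamate receptor subunits in neurons. The comparisons ask how the striatal transcriptome differs when 1 or both copies of the gene are disrupted. Each array carried 45037 probe sets besides 64 controls, and 27022 were bright enough to be tested. Array medians ranged from 143 to 201 in deposited signal, Pearson correlations between arrays across probe sets from 0.965 to 0.996, and no array duplicated another. The number of arrays limits the precision of every value.

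Ptpn5 was read by 2 probe sets, and both followed the genotype. With the brighter the signal was 3527 ± 276 (SD, n = 4) in wild-type striatum, 2503 ± 496 (SD, n = 5) in heterozygotes and 1262 ± 232 (SD, n = 4) in homozygotes. With the dimmer it was 1649 ± 217 (SD, n = 4), 1028 ± 231 (SD, n = 5) and 486 ± 105 (SD, n = 4) in the same order. Homozygotes thus kept 35.8% and 29.5% of the wild-type signal, and heterozygotes 71.0% and 62.3%. In limma, homozygous Ptpn5 fell by 1.49 (SE 0.146) and 1.75 (SE 0.167) on the log2 scale, each with a Benjamini-Hochberg adjusted p of 4.59e-06 over all 27022 probe sets. Heterozygous Ptpn5 fell by 0.51 (SE 0.139) and 0.69 (SE 0.159), with limma p-values of 0.00114 and 0.000414 adjusted over the list alone, that is over the 2 Ptpn5 probe sets, and of 0.204 for each over all probe sets. Every homozygous array lay below every heterozygous array, and every heterozygous array below every wild-type array. The two-sided exact permutation p was 0.0286 for homozygotes against wild type, the smallest that 4 against 4 arrays allow, 0.0159 for heterozygotes against wild type and 0.00794 for homozygotes against heterozygotes, the smallest for 5 against 4. Where the probes lie relative to the disrupted part of the gene was not analysed here.

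**Figure D1:**
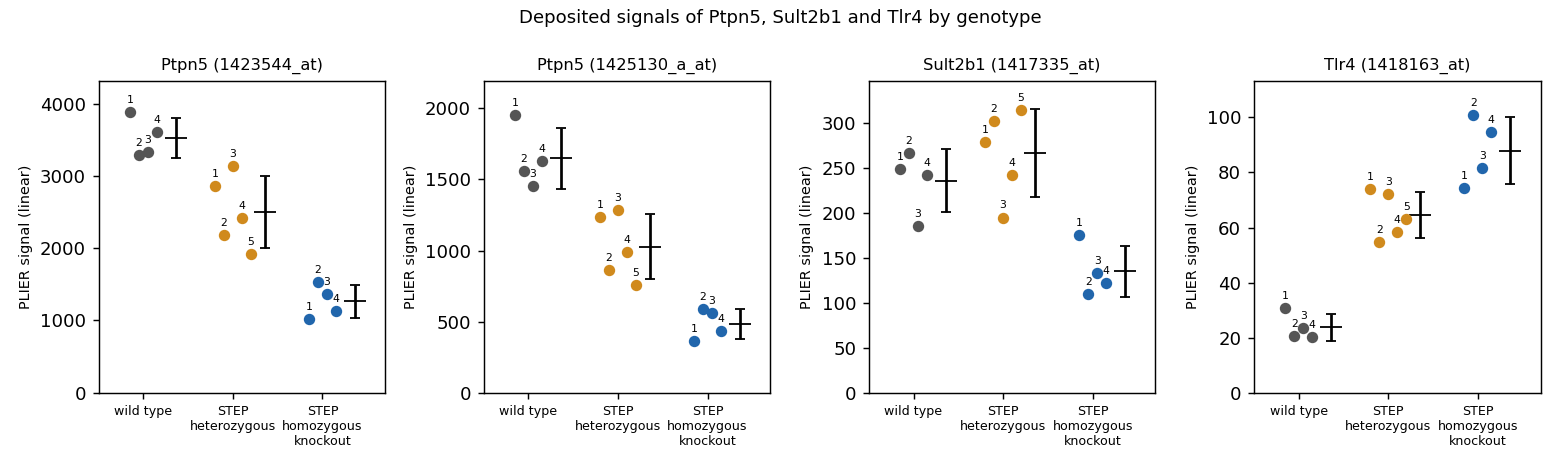
Deposited PLIER signal (linear, y axis) of the Ptpn5 probe sets, of Sult2b1 and of Tlr4 on each array, grouped by genotype on the x axis; numbers are replicate numbers and bars show the mean ± SD. Homozygous Ptpn5 averages 1262 and 486 against 3527 and 1649 in wild type, and Tlr4 rises from 23.8 in wild type to 87.9 in homozygotes near the lower end of the signal range.

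In homozygous against wild-type striatum, Ptpn5 was the only gene to pass. The rises closest to the threshold were in Tagln, an actin-binding protein of smooth muscle and other contractile cells, Egr2, an activity-induced zinc finger transcription factor, and Pitpnm3, of the phosphatidylinositol transfer protein family. Tagln read 208 ± 39.8 (SD, n = 4) in wild type and 474 ± 175 (SD, n = 4) in homozygotes, a log2 difference of 1.08 (SE 0.193, limma adjusted p = 0.0681). Egr2 went from 335 ± 136 to 1195 ± 514, or 1.79 (SE 0.342, adjusted p = 0.116), and Pitpnm3 from 527 ± 20.6 to 889 ± 85.3, or 0.73 (SE 0.141, adjusted p = 0.116). For each of these 3 genes all homozygous arrays lay above all wild-type arrays. The lowest p-values among decreases besides Ptpn5 belonged to the steroid sulfotransferase Sult2b1 (−0.75, SE 0.154, adjusted p = 0.172), the actin-bundling protein Tlnrd1 (−0.86, SE 0.211, adjusted p = 0.818) and the actin-binding kelch protein Klhl1 (−0.55, SE 0.144, adjusted p = 0.8294).

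Over all probe sets, limma with Benjamini-Hochberg adjustment called 0 higher and 2 lower in homozygotes against wild type, both of Ptpn5. At an unadjusted p under 0.05, 724 were higher and 48 lower, so that 93.8% of them were increases. The higher count was 7711 without homozygous array 1, 234 without homozygous array 2, 480 without homozygous array 4 and 372 without wild-type array 4. The deposited scaling carries a median difference of 0.11 over all tested probe sets. After quantile normalization, which removes it, the split was 627 higher and 552 lower, or 53.2% increases, and the calls were the 2 Ptpn5 probe sets and Klhl1 (−0.67, adjusted p = 0.0173). The count depends on which arrays are fitted: without homozygous array 4 it was 10, without heterozygous array 5 it was 7, without heterozygous array 2 it was 5, and without wild-type array 4, heterozygous array 1 or homozygous array 1 it was 4. Leaving out heterozygous array 5 and homozygous array 4 together, chosen after seeing the data, gave 27, with Egr2, Tagln, Fos and Tlnrd1 among them.

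Probe sets below the 40th percentile of mean signal were not tested, and without that filter limma called 2 more genes in homozygotes, chosen for naming after their values were seen. Tlr4, the innate receptor for bacterial lipopolysaccharide, read 23.8 ± 4.86 (SD, n = 4) in wild type, 64.6 ± 8.42 (SD, n = 5) in heterozygotes and 87.9 ± 12.1 (SD, n = 4) in homozygotes. On the log2(signal + 16) scale, which understates changes of dim probe sets, it rose by 1.39 (SE 0.127, adjusted p = 4.48e-06) in homozygotes and by 1.02 (SE 0.120, adjusted p = 0.000569) in heterozygotes. It was the only probe set called in heterozygotes without the filter. Tmem114 rose by 1.07 (SE 0.173, adjusted p = 0.0279) in homozygotes, from 54.3 ± 10.2 to 134 ± 38.9, and its adjusted p was 0.193 after quantile normalization, against 1.22e-05 for Tlr4.

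Activity-induced immediate early genes had a positive median difference in homozygotes, and camera called them only at its preset correlation. Of the 23 measured genes of this list, 22 were higher than in wild type, with a median log2 difference of 0.47 against 0.18 for all named genes. Adjusted over the list alone, 15 rose, led by Egr2, the synaptic pentraxin Nptx2 (0.55, SE 0.146), the AP-1 subunit Fos (1.28, SE 0.346) and the orphan nuclear receptor Nr4a3 (0.70, SE 0.203). Nr4a2, named after its values were seen, fell by 1.21 (SE 0.516), and over all probe sets none of the 23 passed. The competitive test camera called the list higher (adjusted p = 0.000161), but adjusted p = 0.773 with an estimated correlation, and fry gave an adjusted p of 0.123. Leaving out homozygous array 1 gave camera's adjusted p as 0.162, homozygous array 3 as 0.107 and wild-type array 3 as 0.0539, and limma array weights turned the direction (adjusted p = 0.702). Averaged per array after quantile normalization, the list was higher by 0.38 in homozygotes, with a two-sided exact permutation p of 0.114. The names of all these genes come from a table of genes the authors selected on the same arrays, so that these counts are not independent evidence of a direction.

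Cortical excitatory neuron markers and glucocorticoid-responsive genes were the other lists that camera called in homozygotes against wild type. Among 11 cortical markers 6 were higher and 5 lower, with a median of 0.06, while camera, which compares them with the other named genes, called them lower (adjusted p = 0.000497). With an estimated correlation the adjusted p = 0.773, and after quantile normalization the median was −0.06 with an adjusted p of 0.105. Tshz2, a zinc finger transcription factor, rose by 0.88 (SE 0.268) when adjusted over the list alone, while Tbr1 differed by −0.34 (SE 0.348), Neurod2 by −0.25 (SE 0.349) and Bcl6 by 0.20 (SE 0.152). Leaving out wild-type array 2 (adjusted p = 0.138), homozygous array 2 (0.232) or homozygous array 3 (0.107) ended the call. Of 15 glucocorticoid-responsive genes only 3 were measured, all of them named through the authors' table of changes on these arrays. Per1 among them is also counted with the immediate early genes. When adjusted over the list alone all 3 rose: the cell cycle inhibitor Cdkn1a by 0.66 (SE 0.144), the clock gene Per1 by 0.33 (SE 0.154) and the NF-κB inhibitor Nfkbia by 0.27 (SE 0.113). Camera's adjusted p was 0.0123, and with an estimated correlation the adjusted p = 0.567. Fry, which tests against no change, gave an adjusted p of 0.0381, and this was the only list it called in homozygotes. The table that named these genes holds mostly increases. That selection favours a rise, so neither the count nor fry is independent evidence of a direction. Camera's adjusted p was 0.105 after quantile normalization, 0.198 without homozygous array 1, 0.107 without homozygous array 3 and 0.0539 without wild-type array 3.

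The 12 other lists that could be tested did not pass in homozygotes, with camera adjusted p-values from 0.113 for GABAergic interneuron markers to 0.910 for other classical tyrosine phosphatases. The MAP kinase phosphatases Dusp1, Dusp6 and Dusp7 differed by 0.35 (SE 0.188), 0.21 (SE 0.147) and 0.04 (SE 0.129), and Dusp7 turned to −0.08 after quantile normalization. Among STEP substrates and their kinase partners, Src differed by 0.28 (SE 0.15), Grin2b by 0.14 (SE 0.125), Gria3 by 0.15 (SE 0.141) and Mapk11 by −0.08 (SE 0.272), none passing over the list alone. Of 8 glutamate receptor genes 7 were higher and none passed, with Grik1 at 0.40 (SE 0.166), Grin2d at 0.27 (SE 0.128), Gria4 at 0.22 (SE 0.131) and Grm8 at −0.18 (SE 0.130). The 17 presynaptic genes were all higher with a median of 0.13, and 11 of them after quantile normalization (adjusted p = 0.640 as deposited). Adjusted p-values were 0.682 for ERK output genes, for clock genes and for ribosomal proteins, 0.876 for postsynaptic scaffolds, heat shock genes, MAP kinase phosphatases and GABA receptors, 0.657 for glutamate receptors and 0.486 for STEP substrates. Another 8 lists had 1 or 2 measured genes and 9 had none, among them oligodendrocyte, endothelial, choroid plexus, cholinergic and indirect-pathway neuron markers. Camera's direction was downward for MAP kinase phosphatases, other tyrosine phosphatases, STEP substrates, glutamate receptors, presynaptic genes and interneuron markers although their medians lay above 0. The median over all named genes was 0.18. In the untested lists, the 2 microglial genes measured out of 17 rose when adjusted over the list alone (median 0.36). Both were named through the authors' table of changes on these arrays. Alas2, the erythroid enzyme of haem synthesis and the single erythrocyte marker measured, differed by −0.97 (two-sided exact permutation p = 0.257). Alas2 read 781.5 on wild-type array 2, 87.4 to 232 on the other wild-type arrays and 87.8 to 134.9 in homozygotes, so that the difference rests largely on 1 array.

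**Figure D2:**
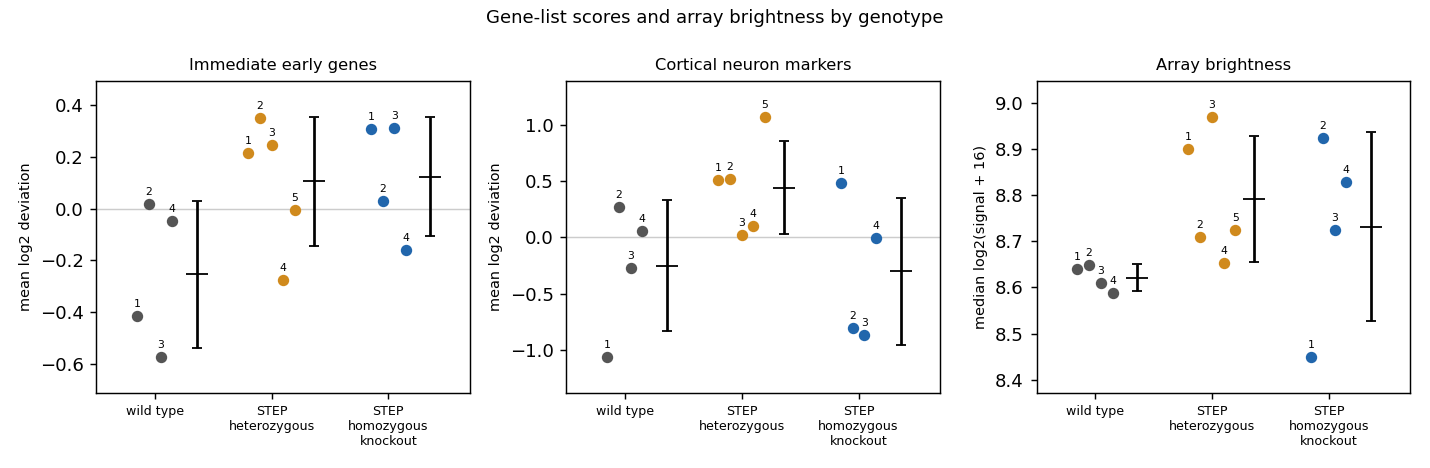
Mean log2 deviation of immediate early genes and of cortical excitatory neuron markers after quantile normalization, and median log2(signal + 16) over tested probe sets as deposited (y axes), for each array by genotype (x axis); numbers are replicate numbers and bars show the mean ± SD. Wild-type medians lie between 8.59 and 8.65 and heterozygous medians between 8.65 and 8.97, and the cortical score of heterozygous array 5 is 1.07.

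In heterozygous against wild-type striatum no gene passed over all probe sets. The lowest p-values among increases were those of Rasl10a, a small Ras-like GTPase, Rps15a, a protein of the small ribosomal subunit, and Rprm, a mediator of cell cycle arrest. Rasl10a read 395 ± 52.5 (SD, n = 4) in wild type and 771 ± 229 (SD, n = 5) in heterozygotes, a log2 difference of 0.90 (SE 0.166, limma adjusted p = 0.138). Rps15a went from 145 ± 28.3 to 245 ± 29.6, or 0.71 (SE 0.134, adjusted p = 0.142), and Rprm from 678 ± 288 to 1603 ± 318, or 1.31 (SE 0.254, adjusted p = 0.153). All heterozygous arrays lay above all wild-type arrays for these 3 genes. Within wild type, Rasl10a and Rprm were lowest on array 1 and highest on array 2, the arrays with the lowest and highest wild-type cortical scores. Rps15a went the other way, highest on array 1 and lowest on array 2. Among decreases besides Ptpn5 the lowest were S100a8, a calcium-binding protein abundant in neutrophils (−1.38, SE 0.615, adjusted p = 0.319), Dpy19l3, a mannosyltransferase (−0.32, SE 0.165, adjusted p = 0.340), and Alas2 (−0.60, SE 0.346, adjusted p = 0.36). S100a8 stood at 839.5 on wild-type array 2 and between 109 and 139 on the other wild-type arrays, and without that array the Alas2 difference was −0.00080.

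Limma with Benjamini-Hochberg adjustment called 0 of 27022 probe sets in heterozygotes, while at an unadjusted p under 0.05 there were 4057 higher and 6 lower, or 99.9% increases. The higher count was 7451 without homozygous array 1 and 6325 without heterozygous array 4. It was 2198 and 2346 without wild-type arrays 1 and 4, and 2138 and 2116 without heterozygous arrays 1 and 3. The median difference over all tested probe sets was 0.16, and the array medians differed by 0.17 (two-sided exact permutation p = 0.0317). Median centring over all 45037 probe sets, done before the filter, left a median difference of 0.04 over those tested. The split then stayed uneven, 2346 higher and 595 lower, or 79.8% increases, with 0 calls. After quantile normalization it was 1091 higher and 1116 lower, or 49.4% increases, again with 0 calls. Adding the cortical score as a covariate, chosen after seeing the data, gave 842 higher and 734 lower for homozygotes against wild type, instead of 627 and 552. For heterozygotes against wild type it gave 598 higher and 636 lower, with 0 calls. Without heterozygous array 4, the dimmest of the 5 in log2 median, limma called 389 probe sets. It called 5 without homozygous array 3, 2 without wild-type array 4 and 1 without heterozygous array 5 or homozygous array 4, and 12 without heterozygous array 5 and homozygous array 4 together, chosen after seeing the data. Those 12 include Rprm, Fos, Egr2, Rasl10a and Rps15a.

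In all 15 tested lists most measured genes were higher in heterozygotes when adjusted over the list alone, neuronal or not, for example 3 of 3 ribosomal proteins, 4 of 4 clock genes and 16 of 17 presynaptic genes. Camera, which compares with the other named genes, called 0 lists, while fry, which compares with no change, called 15. All 11 cortical excitatory neuron markers rose when adjusted over the list alone, with a median log2 difference of 0.93, for example Tbr1 by 1.09 (SE 0.330), Neurod2 by 1.08 (SE 0.331) and the vesicular glutamate transporter Slc17a7, named after its values were seen, by 1.43 (SE 0.376). After quantile normalization all 11 were still higher, with a median of 0.73. All 6 GABAergic interneuron markers rose, with a median of 0.60, among them the neuropeptides Vip by 1.38 (SE 0.336), Sst by 0.38 (SE 0.111) and Npy by 0.31 (SE 0.107). Of 23 immediate early genes 21 rose, with a median of 0.47, including Fos by 1.31 (SE 0.328) and Nptx2 by 0.61 (SE 0.139). Camera's adjusted p was 0.614 for the cortical list, 0.614 for the interneuron list and 0.889 for the immediate early genes, and with an estimated correlation the adjusted p was 0.939, 0.939 and 0.964. Camera's direction for the immediate early genes was downward, against their median. The per-array cortical score was higher by 0.69 (two-sided exact permutation p = 0.0714), and the immediate early gene score by 0.36 (exact permutation p = 0.0873). The genes named were selected by the authors on these arrays, mostly as increases in heterozygotes. The counts of rises and fry's calls therefore partly restate that selection. Of 18 clock genes, for example, only 4 were named. The median over all named genes was itself 0.31.

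Homozygous against heterozygous striatum differed in Ptpn5 and in Sult2b1, which conjugates sulfate to cholesterol and other sterols. The Sult2b1 gene lies 1.35 Mb from Ptpn5 on chromosome 7. Ptpn5 fell by 0.97 (SE 0.139, limma adjusted p = 0.00755) and 1.05 (SE 0.159, adjusted p = 0.00989). Sult2b1 fell by 0.91 (SE 0.146, adjusted p = 0.0190), from 267 ± 48.8 (SD, n = 5) to 135 ± 28.4 (SD, n = 4), with 236 ± 35.1 (SD, n = 4) in wild type. Its call ended after quantile normalization (−0.86, adjusted p = 0.885) and without any of heterozygous arrays 1 and 2 or homozygous arrays 2, 3 and 4, with adjusted p-values up to 0.224. The Sult2b1 difference itself stayed between −1.02 and −0.82 without 1 array. Limma called 0 higher and 3 lower in all, and at an unadjusted p under 0.05 there were 73 higher and 713 lower, against 711 higher and 771 lower after quantile normalization. Median centring, done before the filter, left a median difference of −0.03 over the tested probe sets and an uneven split, with 356 higher and 1322 lower. Without homozygous array 1 there were 525 higher and 495 lower as deposited, an imbalance no longer seen. Array weights gave the other direction, 6398 higher and 3040 lower, with a median difference of 0.04. The lower count was 1097, 416 and 1234 without homozygous arrays 2, 3 and 4, and 1264 without heterozygous array 4. Without heterozygous array 4 there were 5 calls, and leaving out heterozygous array 5 and homozygous array 4 together gave 24.

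Cortical excitatory neuron markers and GABAergic interneuron markers had negative median differences between homozygotes and heterozygotes, and camera called both lists only at its preset correlation. Of 11 cortical markers 8 fell when adjusted over the list alone, with a median of −0.90, for example Tbr1 by −1.43 (SE 0.330) and Neurod2 by −1.33 (SE 0.331), and camera called the list lower (adjusted p = 0.00292), but adjusted p = 0.705 with an estimated correlation. Of 6 interneuron markers 5 fell, with a median of −0.59, and Npy by −0.39 (SE 0.107, camera adjusted p = 0.0332, and 0.705 with an estimated correlation). Camera called immediate early genes higher (adjusted p = 0.000189), although their median was −0.02 and none passed over the list alone; the named genes as a whole had a median of −0.15. With an estimated correlation the adjusted p for immediate early genes was also 0.705. After quantile normalization the adjusted p was 0.103 for cortical and 0.180 for interneuron markers. The cortical call ended without homozygous array 2 (adjusted p = 0.144), the immediate early gene call without homozygous array 3 (0.194), and the interneuron call without homozygous array 4 (0.251), homozygous array 2 (0.0662), homozygous array 3 (0.0529) or heterozygous array 4 (0.0586). The cortical score was lower by −0.74 in homozygotes than in heterozygotes (two-sided exact permutation p = 0.0714). All these markers were named through the authors' table, most of whose entries are increases in heterozygotes on these arrays. All 11 cortical and all 6 interneuron markers were higher in heterozygotes than in wild type. That selection favours falls from heterozygotes to homozygotes, so the counts and the score are not independent evidence of a direction. The 3' to 5' log2 ratios of the Gapdh and actin control probe sets, which follow RNA quality, differed in the same comparison by −0.047 (exact permutation p = 0.0238) and −0.085 (p = 0.0556).

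Heterozygotes were also set against the midpoint of wild type and homozygotes on the log2 scale, which lies below the midpoint of the signals themselves. Ptpn5 differed from the log2 midpoint by 0.23 (SE 0.118, adjusted p = 0.559) and 0.18 (SE 0.135, adjusted p = 0.605). The midpoints of the mean signals, which an additive dose would give, were 2394 and 1067, against heterozygous means of 2503 and 1028, a comparison made after the values were seen and not tested. Limma called 0 probe sets off the midpoint, with 2469 higher and 15 lower at an unadjusted p under 0.05 and 1141 higher and 967 lower after quantile normalization. With the cortical score as a covariate after quantile normalization, chosen after seeing the data, there were 551 higher and 564 lower. Median centring, done before the filter, left a median difference of 0.04 over the tested probe sets and an uneven split, with 2401 higher and 439 lower. As deposited, the higher count was 4262 without heterozygous array 4 and 4190 without homozygous array 2, and 1326 and 1335 without heterozygous arrays 1 and 3. Rasl10a (0.73, SE 0.141), Rprm (1.12, SE 0.216) and Tbr1 (1.26, SE 0.281) each had an adjusted p of 0.144. Without heterozygous array 4 the count was 257, without wild-type array 4 it was 5, without homozygous array 4 it was 2 and without homozygous array 1 it was 1. Leaving out heterozygous array 5 and homozygous array 4 together gave 25.

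The homozygous and heterozygous effects shared their wild-type arrays. Across the 27022 tested probe sets, which are not independent replicates, the log2 differences had a Pearson correlation of 0.526 and a covariance of 0.00819. In 100 simulations with no effect and the same sharing, the median correlation was 0.579 and the mean covariance 0.00786, and 58 correlations and 37 covariances were at least as large as observed. With the wild-type arrays split into sets of 2, the correlation was between −0.06 and 0.391, with a median of 0.136 over 6 assignments. At an unadjusted p under 0.05, 404 probe sets were higher in both, Fos and Cdkn1a among them. Independent lists would share 109, and the simulations gave a median of 11 and up to 8850. Of the 6 lower in heterozygotes 4 were lower in both, Ptpn5 included, where independent lists would share 0.0107 and the simulated median was 9.

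Ptpn5 lies on chromosome 7, and probe sets near it were compared with the rest because a targeted locus can carry flanking sequence of another strain. Among tested probe sets with a gene name and position, 24 lay within 10 Mb of Ptpn5 and 2875 elsewhere. The 2 called in homozygotes against wild type were both Ptpn5 itself, so that 0 of its neighbours were called in that comparison. Sult2b1, called between homozygotes and heterozygotes, lies 1.35 Mb from Ptpn5, inside this window. The two-sided Fisher exact p of 6.57e-05 counts Ptpn5, the disrupted gene itself, and so says nothing about its neighbours. In the authors' deposited table, the share of decreases in homozygotes was then compared across chromosomes, a comparison chosen after seeing the data. With Ptpn5 left out, 14 of 85 listed probe sets on chromosome 7 were lower, or 16.5%, against 33 of 678 on the others, or 4.87% (odds ratio 3.84, two-sided Fisher exact p = 0.000255, not adjusted for the 20 chromosomes). The 14 read 13 genes, among them Sult2b1, Tlnrd1, Nav2, Cep89 and Dpy19l3.

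**Figure D3:**
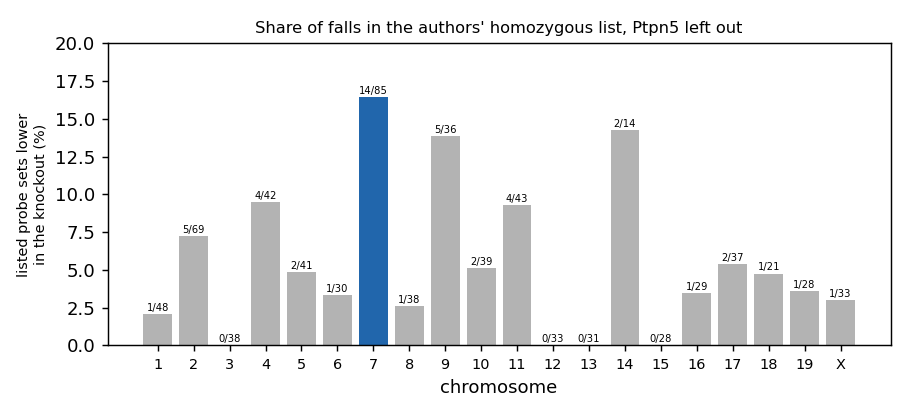
Share of probe sets listed for homozygotes in the authors' deposited table that were lower than in wild type (percent, y axis), by chromosome (x axis), with Ptpn5 left out; the numbers above the bars give decreases over listed probe sets. Chromosome 7 has 14 of 85, or 16.5%, and the other chromosomes together have 4.87%.

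The authors' deposited table of changed genes lists 1027 probe sets for homozygotes, 963 higher and 64 lower, and 3874 for heterozygotes, 3848 higher and 26 lower, with 478 in both. All have a fold of at least 1.2 and an unadjusted p of at most 0.05 in the authors' deposited table, while an adjusted p under 0.05 was reached by 3 in homozygotes and 1 in heterozygotes. In the authors' deposited table Tlr4 has folds of 3.72 (adjusted p = 2.7e-06) and 2.74 (adjusted p = 0.000113), and Ptpn5 has homozygous folds of −3.44 (adjusted p = 6.33e-05) and −2.82 (adjusted p = 0.000111). Of the listed probe sets, 615 were tested here in homozygotes and 3183 in heterozygotes, and every one had the same sign. At an unadjusted p under 0.05, 607 and 3161 of them were shared, and after quantile normalization 426 and 1018. Egr2, Fos, Tagln and Sult2b1 are among the shared homozygous entries. This overlap is a description and not independent evidence, since the arrays are the same.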

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

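Of the tests in this part, those of array medians against gene dose, of decreases on chromosome 7 and of cortical markers were chosen only after the result was seen, while the regroupings of arrays and the spiked controls were set beforehand.

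Among heterozygous probe sets at an unadjusted p under 0.05, 4057 were higher and 6 lower. Quantile normalization evened this to 1091 and 1116, while median centring left 2346 and 595. Median centring was done before the filter and left a median difference of 0.04 over the tested probe sets. The 9 spiked hybridization control probe sets, which are added with the labelled cRNA and owe nothing to the tissue, were also higher on the heterozygous arrays, by 0.21 (SE 0.085, exact permutation p = 0.0714), against 0.01 on the homozygous arrays. Brighter hybridization or scanning of the heterozygous arrays is therefore a candidate explanation for the shift of 0.16 over all tested probe sets. The spiked controls of heterozygous arrays 2 and 4 (log2 11.28 and 11.31) lay inside the wild-type range of 11.20 to 11.35, however. Homozygous array medians were higher than wild type by 0.11 (exact permutation p = 0.343) without brighter spiked controls. A rise that follows the dose of the Ptpn5 allele cannot be told apart from brighter hybridization or scanning here. The array medians of homozygotes and heterozygotes differed with an exact permutation p of 0.619. With 4 and 5 arrays, and homozygous medians from 8.45 to 8.92, that test could hardly go against a dose effect and decides nothing.

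On chromosome 7 the authors' deposited table holds more decreases in homozygotes than elsewhere, 14 of 85 against 33 of 678 with Ptpn5 left out. Among named probe sets at an unadjusted p under 0.05 in limma without a filter, it was 14 of 84 against 29 of 660 (odds ratio 4.34). All named probe sets come from the same deposited table, so this is not an independent selection. After quantile normalization the odds ratio among these named probe sets was 3.12 (14 of 71 against 38 of 522, Fisher p = 0.00250). Adding the cortical score left 2.73 (15 of 84 against 49 of 666, Fisher p = 0.00301). Only named probe sets have a position here, while 971 in all were lower after quantile normalization without a filter. Decreases among unnamed probe sets are therefore not counted. These tests cannot decide whether unequal array scaling or cortical tissue in the dissections accounts for the excess. Within 20 Mb of Ptpn5, 7 of 29 listed probe sets were lower, against 7 of 56 on the rest of the chromosome (Fisher p = 0.220). Against 40 of 734 in the rest of the genome, the odds ratio was 5.497 (Fisher p = 0.00119). That comparison does not separate nearness to Ptpn5 from the excess on the whole chromosome. In the heterozygous list chromosome 7 had no excess, 1 of 236 against 12 of 2892 (odds ratio 1.02), but so few decreases cannot decide. The decreases may or may not gather near the gene, and donor-strain sequence flanking the targeted allele stays open. Probe sequences and strain variants, which might bear on it, were not analysed here.

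Cortical markers varied widely between arrays of the same genotype, and the 11 measured markers moved together within genotypes, with a mean residual correlation of 0.588. The median of 10000 random named gene lists of that size was 0.258 and their 95th percentile 0.471. Varying amounts of cortical tissue in the dissected striatum could account for this, as a hypothesis from these data. The number of Ptpn5 alleles is the same on all arrays of a genotype and cannot produce a spread within it, and no other biological explanation was tested.

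Regrouping the arrays gave the following counts, with the real grouping included. For homozygotes against wild type, 4 of 35 regroupings gave at least the real 2 calls and the highest other gave 70, so chance is not excluded for the count, and a regrouping with so many calls points to a structure among the samples other than genotype. For homozygotes against heterozygotes, 12 of 100 gave at least the real 3, and the highest other gave 15200, again a structure of the samples. That regrouping set heterozygous arrays 1 and 3 and homozygous arrays 2 and 4 against the rest. Their log2 medians were the highest of these genotypes, 8.83 to 8.97 against 8.45 to 8.72, so its count goes with array brightness. For heterozygotes against wild type and off the midpoint the real count was 0, so that 100 of 100 were at least as large whatever the arrays, which says nothing about chance; the highest others were 875 and 292, which point to a structure of the samples too. For gene lists, 15 of 35 gave at least the real 3 in homozygotes (highest other 6), and chance is not excluded there. In heterozygotes the real list count of 0 again fixes 100 of 100 (highest other 6).

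Single arrays stood far from the rest of their genotype in 14 of 177 groups of values looked at, where chance gives about 1 in 20, or 8.85; some of those genes were picked after their values were seen, so the 14 are not an unbiased count. On the first principal component heterozygous array 5 lay at 32.5 and the others between −2.79 and 4.47. S100a8 was 839.5 on wild-type array 2 and 1329.5 on homozygous array 4, against at most 139 and 56.7 on the others. S100a9, chosen after its values were seen like Lcn2, Dlk1 and Nav2, was 235 on wild-type array 2 and 358 on homozygous array 4, and Lcn2 was 2438 on homozygous array 4 against at most 17.1 on the other homozygous arrays, with 2443 and 599.8 on wild-type arrays 2 and 3. Dusp1 was 1677 and Bcl6 469 on wild-type array 2, and Dusp6 was 1183 on heterozygous array 4. Dlk1 was 72.7 on heterozygous array 2. Nav2 was 212 on wild-type array 3 and 10.8 on homozygous array 4, where the other homozygous arrays read 143 to 155. The unnamed probe sets 1457557_at and 1440557_at stood apart on wild-type array 4, at 279 against 84.3 to 94.95 and at 67.9 against 386 to 437.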

How the results depend on the processing

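The alternatives that combine quantile normalization with no filter or a cortical score, and the one without heterozygous array 5 and homozygous array 4, were chosen only after the result was seen, and the cause of each change named here was not tested. With p adjusted over the 2 Ptpn5 probe sets alone, both kept direction and side of the threshold in both genotypes under every alternative run. Over all probe sets heterozygous Ptpn5 did not pass in the main fit (limma adjusted p = 0.204 for each). The differences of the dimmer without 1 array went from −1.84 to −1.62 in homozygotes and −0.78 to −0.59 in heterozygotes. Array weights gave the largest counts of changed probe sets: 6439 for homozygotes against wild type, 1331 for heterozygotes against wild type, 5368 for homozygotes against heterozygotes, 2785 off the midpoint, and 2 lists in heterozygotes. Fitting only the groups compared gave 33 and 29 for the homozygous comparisons, no filter 4 and 1 for homozygotes and heterozygotes against wild type, a threshold of 0.10 also 4 and 1, and 1 probe set per gene 1 for homozygotes. Quantile normalization without a filter gave 4 and 1, and with the cortical score added again 4 and 1. Leaving out heterozygous array 5 and homozygous array 4 together gave 27, 12, 24 and 25 for the same 4 comparisons, and 1 list in heterozygotes. Leaving out 1 array gave 2 to 10 (10 without homozygous array 4, 7 and 5 without heterozygous arrays 5 and 2), 0 to 389 (389 without heterozygous array 4), 2 to 5 (5 without heterozygous array 4) and 0 to 257 (257 without heterozygous array 4), with 0 to 4 lists in homozygotes and 0 to 1 in heterozygotes. Lists called in homozygotes numbered 1 after quantile normalization, 0 with an estimated correlation and 1 with fry, and fry called 15 in heterozygotes. The correlation of effects ranged from 0.36 without homozygous array 4 to 0.668 without wild-type array 3, and was 0.136 with the wild-type arrays split. Overlap with the authors' deposited table was 922 for homozygotes without the filter, and for heterozygotes 1018 after quantile normalization and 1428 when the filter was dropped too. Immediate early genes in homozygotes reversed under array weights (adjusted p = 0.702). Fry, which tests against no change and so asks another question than camera, had the other sign for cortical markers in homozygotes (0.790) and immediate early genes between homozygotes and heterozygotes (0.867). Dusp7 turned to −0.075 after quantile normalization, −0.054 after median centring, −0.086 with array weights, −0.037 without the 2 arrays and −0.064 with the cortical covariate, and ranged from −0.037 to 0.11 without 1 array. Sst turned to −0.039 with array weights, Mapk11 ranged from −0.35 to 0.14 and Neurod2 from −0.65 to 0.023 without 1 array. Of 866 values of named genes, 773 kept direction and side of the threshold, 71 passed it newly, 8 of Sult2b1 no longer passed it and 14 reversed.

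What the replicate numbers stand for is not given in the sources used here, and they were not treated as pairs. Of 12 same-numbered pairs from different genotypes, 3 had deviations correlated above 0.1, in a range from −0.55 to 0.224, and 0 arrays matched best with their own number in another genotype. With the replicate number as a block limma called 57 probe sets for homozygotes against wild type, 50 for heterozygotes against wild type, 44 for homozygotes against heterozygotes and 54 off the midpoint, and camera called 2 lists in heterozygotes. Only heterozygous array 5 has replicate number 5, so that array adds nothing to the contrasts of the block fit. Within 10 Mb of Ptpn5 the block called 2 probe sets of other genes for homozygotes against wild type, with 36 elsewhere among those with a position. Dim probe sets limit these arrays: a filter at the 40th percentile removed Tlr4.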

Other observations

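The tests in this part were all chosen only after the data had been seen.

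The genes named in the authors' deposited table were not spread evenly over the gene lists. Of 32 activity-induced immediate early genes, which neurons transcribe within minutes of firing, 25 were named there (78.1%), against 21.8% of the genes of the other lists (Fisher exact test, adjusted p = 4.07e-09). Of 24 genes of the presynaptic vesicle machinery 18 were named (75%, adjusted p = 3.7e-06), and of 16 cortical excitatory neuron markers 11 (68.8%, adjusted p = 0.00267). Interferon-stimulated and MHC class I genes had 0 of 20 named (adjusted p = 0.0237). Of 25 pan-striatal medium spiny neuron genes 2 were named (adjusted p = 0.116), and of 11 indirect-pathway markers 0 (adjusted p = 0.190). The test takes genes as independent although genes of a list can move together, as the cortical markers did within genotypes (mean correlation 0.588), and the immediate early and cortical lists lost their camera call in homozygotes with an estimated correlation (adjusted p = 0.773 for each), so these p-values only describe the table. A gene can be named for a change in either genotype, and most entries are increases in heterozygotes. The shares also take no account of how brightly a gene is read or how many probe sets read it.

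For the decreases on chromosome 7 the heterozygous share of the homozygous difference varied between probe sets. After quantile normalization the heterozygous difference was a median of 23.3% of the homozygous difference over the 14 probe sets, with 5 of them above both Ptpn5 values and Csrp3 at 106%, 39.9% over the 33 decreases on other chromosomes, and 47.6% and 43.4% for the Ptpn5 probe sets; the difference between these shares was not tested. Without the filter and after quantile normalization, Nav2 differed by −1.43 in homozygotes and −0.17 in heterozygotes on a probe set that read 10.8 on homozygous array 4, and by −0.10 and 0.14 on a brighter probe set. Cep89 differed by −0.84 and −0.28 on a probe set and by −0.41 and −0.25 on another, the latter a share of 59.6%. None of these had an adjusted p under the threshold.

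The probe sets 1457557_at and 1440557_at, which have the lowest heterozygous p among unnamed probe sets in each direction and were picked after their values were seen, separated the mutant arrays from 3 of the 4 wild-type arrays in opposite directions. 1457557_at read between 280.5 and 353 on all 9 heterozygous and homozygous arrays, 279 on wild-type array 4 and 84.3 to 94.95 on the other wild-type arrays. 1440557_at read between 56.5 and 97.4 on the same 9 arrays, 67.9 on wild-type array 4 and 386 to 437 on the others. Wild-type array 4 had a Ptpn5 signal of 3608 in the brighter probe set, inside the wild-type range.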
